A study of Mus musculus with 7 samples.

How the data were processed

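Chromatin immunoprecipitation libraries of mouse 3T3 fibroblasts and P19 embryonal carcinoma cells were made with the CTCF antibody N2.2 or the CTCFL antibody S6, per the labels. Per the labels' protocols, cells with the inducible construct were kept in 2 µg/ml doxycycline and induced by 48 h without it, and libraries were made from 10 ng of DNA. The submitters' processing notes name FastQC, Bowtie, SAMtools, MACS 1.4 and the builds hg19 and mm9, with no roles. Aligner settings, read filters, read depth and the control library used in peak calling are not given in the sources used here. Each of the 4 samples analysed here has 1 deposited peak list, and pooling of libraries is not recorded.

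Each deposited list gives the chromosome, start and end of every peak and, in its last column, the score of the authors' peak caller. The score is read here as −10 times the log10 of the caller's p-value, from the tool the notes name and a lowest value of 50. It depends on depth and on the control library, so it was used only to rank, filter or describe peaks within a list. In the 3T3 CTCF list 505 peaks, and in the 3T3 CTCFL list 4, had a score of exactly 3100, so scores near the top do not rank peaks. Starts were converted to positions counted from 1.

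The build was taken as mm9 from the notes and the organism. The only reference used here was a gene table of another build, GRCm38.p6, and on 10 of 20 chromosomes the last peak lay beyond its last gene. Gene, promoter and motif analyses that were planned for a matching build were not run, no peak was assigned to a gene, and the planned gene lists were not used.

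Peak sets were compared by overlap of at least 1 bp. A share of peaks has an exact (Clopper-Pearson) 95% interval, which covers counting error only, since neighbouring peaks are not independent and there is 1 library per group. Chance overlap came from 1000 circular shifts within chromosomes and, chosen after the data were seen, 1000 shifts of each peak by 20 to 100 kb. Differences of shares have intervals combined from the exact ones. Peak classes were compared within a list by medians, the share of pairs in which the peak with the partner was higher (interval from 200 resamples), and the rank of the class median among 10000 random classes. Score groups are 10 groups of nearly equal size, and 100 random placements gave the chance spacing. Averages over score groups are weighted means of the group differences. The weights are the peaks with CTCFL in each group for CTCF lists, and the peaks without CTCF for CTCFL lists. Rank correlations are across peaks, which are not independent replicates, with intervals from 1000 resamples.

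The named regions followed a rule set before the data were examined. Per line these were the 6 highest scoring CTCFL peaks with CTCF, the 6 without and the 4 highest scoring CTCF peaks without CTCFL, plus the 6 CTCFL peaks without CTCF in both lines with the highest summed rank. The text gives most of them. The densest 1 Mb windows were added after the data were seen, as were the split of CTCF recurrence by CTCFL and by score group and the merged regions.

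Alternatives were other overlap criteria, score limits, equal list lengths, resized peaks, autosomes only and comparisons within 4 equal groups of width or score. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, bedtools 2.31.1 and matplotlib 3.10.9 were used. On the lists and on simulated data, 24 of 24 overlap counts equalled those of bedtools, and overlaps planted among 5866 simulated peaks at 10.0%, 40.0% and 70.0% were recovered. One mitochondrial peak of the 3T3 CTCFL list, positions 1 to 1695 with a score of 141, was kept in the counts and left out of the chromosome comparison.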

Results

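The series mapped the binding of CTCF, a zinc-finger protein that organises chromatin loops and insulates genes, and of its germline paralogue CTCFL (also called BORIS) in mouse cells by chromatin immunoprecipitation and sequencing. NIH3T3 fibroblasts (3T3 below) and P19 embryonal carcinoma cells, a teratocarcinoma line with stem cell properties, were the 2 cell lines. Of the 7 samples, 4 are analysed here, each as 1 peak list: CTCF and CTCFL in 3T3 cells that carried an inducible tagged mouse Ctcfl construct, and CTCF and CTCFL in P19 cells. The P19 titles call those cells controls although their labels also list the Ctcfl construct, so whether CTCFL was induced in P19 is unsettled. CTCF and CTCFL in 3T3 cells without the construct, and P19 input DNA, were not analysed here. Neither CTCFL list was thus checked against cells without the construct, so background of the antibody is not excluded. Below, a bound site is one that holds a peak in the list.

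Each group had 1 library, so no difference below has a replicate check and no p-value is given. Exact (Clopper-Pearson) 95% intervals cover counting error only. Read depth was not given in the sources used here, so the depth behind each peak is unknown. The 3T3 CTCF list held 45653 peaks covering 18.5 Mb, and the 3T3 CTCFL list 16764 peaks covering 5.80 Mb. In P19 there were 32277 CTCF peaks over 20.8 Mb and 5866 CTCFL peaks over 3.58 Mb. Median peak width was 342 bp for 3T3 CTCF, 283 bp for 3T3 CTCFL, 636 bp for P19 CTCF and 581 bp for P19 CTCFL. The authors' peak score, −10 times the log10 of the caller's p-value, had medians of 104, 83.7, 117 and 75.1 in the same order, and is used only within a list. Positions are mm9 coordinates.

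The first comparison asked how much of CTCFL binding falls on CTCF sites. On the full lists most CTCFL peaks lay on a CTCF peak of the same cell line. In 3T3 cells 10270 of 16764 CTCFL peaks overlapped a CTCF peak, 61.3% (95% interval 60.5 to 62.0). In P19 cells 3964 of 5866 did, 67.6% (66.4 to 68.8). Peaks moved by circular shifts along their chromosome overlapped in 1.47% of cases in 3T3 and 1.76% in P19, and shifts of only 20 to 100 kb, which keep the regional density, gave 3.98% and 3.88%. The measured shares were 15.4 and 17.4 times the local chance values. They were below a majority with every list limited to its 5866 highest scoring peaks, at 45.9% in 3T3 and 28.1% in P19, and the 3T3 share was 50% with peak centres within 200 bp.

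Scores of 3100 and above do not rank sites, and the 6 leading 3T3 CTCFL sites with CTCF were all in that range. They lay at chromosome 4 125998756 to 125999151 (score 3205), chromosome 5 151476086 to 151476569 (score 3176), chromosome 15 101930504 to 101931339, chromosome 16 32877513 to 32878312, chromosome 15 97614604 to 97615386 and chromosome 2 29475067 to 29475583 (score 3100 each), and each carried a peak in all 4 lists. In P19 the strongest CTCFL site was at chromosome 11 97420653 to 97421272, with a score of 1059 for CTCFL and 721 for CTCF. In 3T3 it was also bound by both factors, with a CTCF score of 91.2 (list median 104) and a CTCFL score of 112 (list median 83.7). The next P19 site, chromosome 15 82089688 to 82090404 (score 679), was bound by both factors in both lines. Another pair of leading P19 sites, chromosome 11 96882829 to 96884181 (score 633) and chromosome 11 120766653 to 120767182 (score 603), had CTCF but no CTCFL peak in 3T3.

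**Figure D1:**
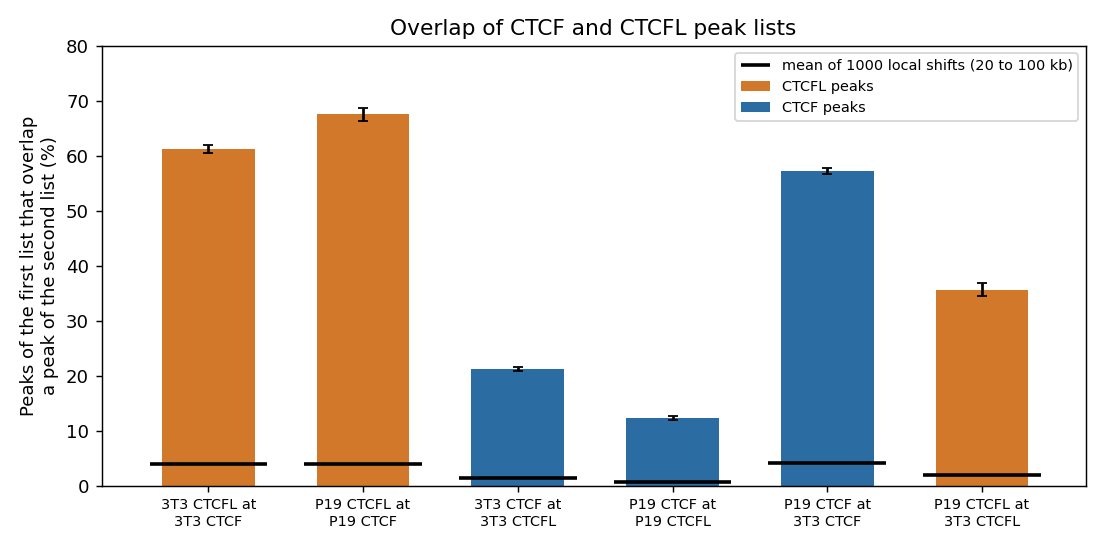
Percent of peaks of the first list that overlap a peak of the second by at least 1 bp, with exact 95% intervals; CTCFL lists are orange, CTCF lists blue, and black lines are the mean of 1000 local shifts of 20 to 100 kb. Every bar stands far above its chance line, with 61.3% for 3T3 CTCFL at CTCF and 67.6% for P19 CTCFL at CTCF.

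Seen from the CTCF side, a minority of CTCF peaks overlapped a CTCFL peak. In 3T3, 9660 of 45653 CTCF peaks had CTCFL, 21.2% (20.8 to 21.5), against 1.45% after local shifts. In P19, 3971 of 32277 had it, 12.3% (11.9 to 12.7), against 0.703%. CTCF sites with the highest scores and no CTCFL included chromosome 7 25918108 to 25918500 in 3T3 (score 3226) and chromosome 9 121923187 to 121923895 in P19 (score 1598), and both were CTCF peaks without CTCFL in the other line as well. A P19 CTCF site at chromosome 7 150104944 to 150105733 (score 1123) had no peak of either factor in 3T3. With every list limited to its 5866 highest scoring peaks, the shares were 43.4% in 3T3 and 27.9% in P19, and with scores of at least 100 in both lists they were 18.8% and 5.85%.

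Sites with both factors had higher scores and wider peaks than sites with either alone, although the width difference of P19 CTCFL was small. The median CTCF score in 3T3 was 233 with CTCFL and 94.2 without, and the CTCF peak with CTCFL was the higher in 72.5% of pairs (71.9 to 73.0). For P19 CTCF the medians were 190 and 111 (69.6% of pairs, 68.8 to 70.3). CTCFL peaks with CTCF had a median score of 101 against 68.2 without in 3T3 (74.6% of pairs, 73.9 to 75.4), and of 81.0 against 66.3 in P19 (63.7% of pairs, 62.3 to 65.1). Median widths with and without the partner were 542 and 312 bp for 3T3 CTCF, 332 and 247 bp for 3T3 CTCFL, 707 and 626 bp for P19 CTCF, and 597 and 552 bp for P19 CTCFL. The wider P19 CTCFL peak was the one with CTCF in 55.8% of pairs (54.3 to 57.3), and in 51.5% when pairs were compared within 4 groups of score. All 8 class medians with the partner exceeded all of 10000 random classes of the same size from the same list. A wider peak also has a greater chance of overlapping another.

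The share of CTCF peaks with CTCFL rose with the CTCF score. In 3T3 it went from 9.04% (8.23 to 9.91) among the lowest scoring of 10 equal groups of peaks to 60.9% (59.5 to 62.3) among the highest. In P19 it went from 4.74% (4.03 to 5.53) to 33.7% (32.1 to 35.4). The reverse share, of CTCFL peaks with CTCF, reached 98.1% (97.3 to 98.7) in the highest 3T3 group and 89.4% (86.7 to 91.8) in the highest P19 group. It was lowest at 37.7% in 3T3 and 53.2% in P19.

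Comparing the lines, 18453 of 32277 P19 CTCF peaks were CTCF peaks in 3T3, 57.2% (56.6 to 57.7), against 4.10% after local shifts. Of the P19 CTCFL peaks, 2093 of 5866 were CTCFL peaks in 3T3, 35.7% (34.5 to 36.9), against 1.94%. Taken from 3T3, 41.7% of CTCF peaks (41.2 to 42.1) and 13.3% of CTCFL peaks (12.8 to 13.8) recurred in P19. P19 CTCFL peaks lay on 3T3 CTCF sites in 67.5% of cases (66.3 to 68.7), whereas only 17.1% of 3T3 CTCFL peaks (16.5 to 17.7) lay on P19 CTCF sites. With lists of 5866 peaks each, recurrence of P19 peaks in 3T3 was 31.3% for CTCF and 26.7% for CTCFL.

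Recurrence of CTCF sites differed with the presence of CTCFL, in opposite directions in the lines. In 3T3, CTCF peaks with CTCFL were P19 CTCF peaks in 28.0% of cases and those without in 45.4%, a difference of −17.4 points (−18.4 to −16.3). In P19, CTCF peaks with CTCFL were 3T3 CTCF peaks in 77.0% of cases and those without in 54.4%, a difference of 22.6 points (21.2 to 24.1). An average over 10 score groups was taken with each group weighted by its number of peaks with CTCFL. The difference was then −37.7 points in 3T3 (−38.6 to −36.8) and 10.3 points in P19 (8.82 to 11.7). Comparing peaks of like score thus widened the 3T3 difference and narrowed that of P19. In 3T3 the shares were 13.1% against 75.8% in group 8 and 71.1% against 91.5% in the highest group. In groups 1 to 7 the share with CTCFL was only 3.20 to 7.28%. Local shifts of all 3T3 CTCF peaks with CTCFL gave 3.84%, and chance was not computed by score group. The intervals of groups 1 to 4 included 3.84%, and those of groups 5 to 7 lay above it, with 7.28% (5.71 to 9.12) in group 7. In P19 the shares were 58.9% against 32.9% in group 2 and 91.2% against 85.7% in the highest group. With peak centres within 200 bp as the criterion the P19 difference was 15.1 points.

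**Figure D2:**
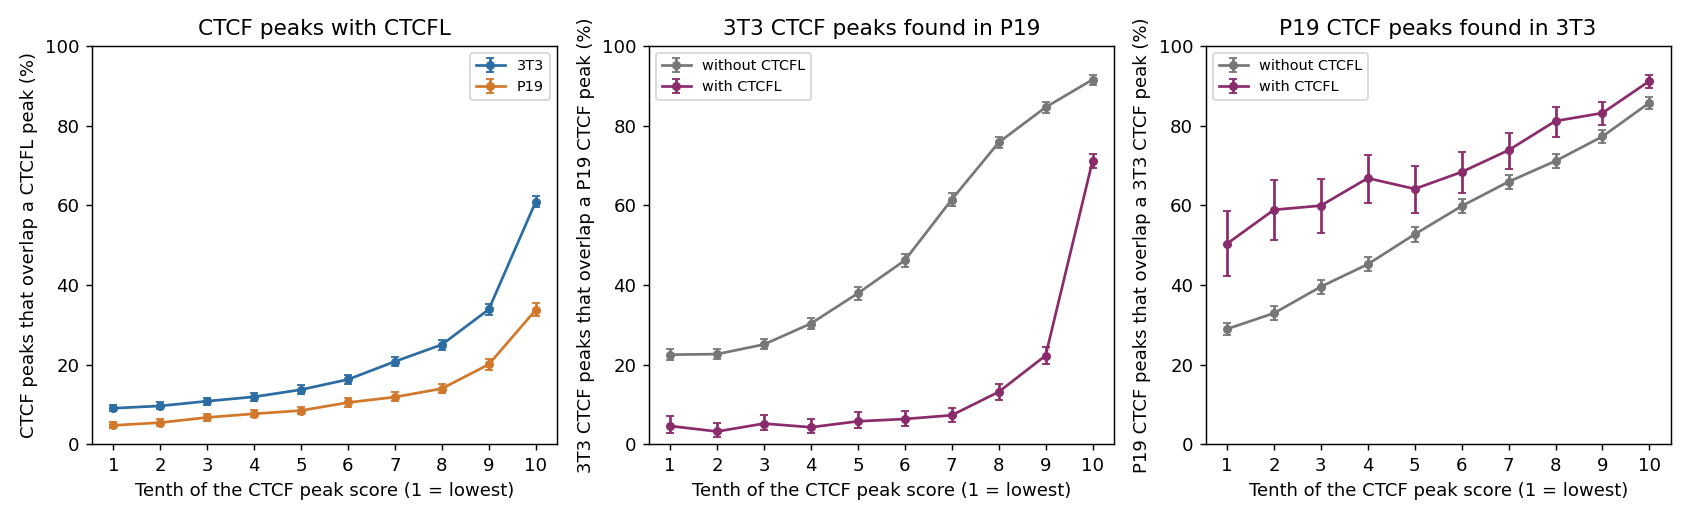
CTCF peaks divided into 10 groups by score (x axis, 1 lowest), with the percent that overlap a CTCFL peak of the same line (left) and the percent that are CTCF peaks of the other line, with and without CTCFL, for 3T3 (middle) and P19 (right); bars are exact 95% intervals. In 3T3 the peaks with CTCFL lie below those without in every group, and in P19 above.

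CTCFL peaks without CTCF numbered 6494 in 3T3 and 1902 in P19, and fared differently in the other line. Of the 3T3 peaks, 141 were P19 CTCFL peaks, 2.17% (1.83 to 2.56), against 0.636% after local shifts. P19 CTCF peaks lay at 120, 1.85% (1.53 to 2.21), against 1.26% after circular shifts and 2.80% after local shifts. Shifted peaks could land on 3T3 CTCF sites, which this class lacks by definition, and 57.2% of P19 CTCF peaks were such sites. These chance values are therefore likely too high for the class, and whether 1.85% exceeds chance cannot be told from them. Of the P19 peaks, 740 were 3T3 CTCFL peaks, 38.9% (36.7 to 41.1), and 905 were 3T3 CTCF peaks, 47.6% (45.3 to 49.9). CTCFL sites that lacked a CTCF peak in P19 thus often had one in 3T3, but less often than P19 CTCFL peaks with CTCF (77.0%, 75.7 to 78.3). Of the 740, 663 also had CTCF in 3T3, 89.6% (87.2 to 91.7). That share was not particular to these sites, since 2091 of the 2232 3T3 CTCFL peaks found in P19 had CTCF in 3T3. No peak of either factor in the other line was found for 6278 of the 3T3 peaks, 96.7%, and 920 of the P19 peaks, 48.4%. Among 3T3 peaks scoring at least 100, recurrence as P19 CTCFL was 5.41%, and with no CTCF peak within 1000 bp, overlap with P19 CTCF was 0.936%. With peak centres within 200 bp, which also changes which peaks count as lacking CTCF, these shares were 4.02% and 3.29%.

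The strongest 3T3 CTCFL site without CTCF, chromosome 15 88919522 to 88920164, scored 1190 and had a CTCFL peak in P19 at a score of 56.3. Chromosome 2 152222568 to 152223396 (score 649), chromosome 18 36961148 to 36961732 (score 522) and chromosome 10 80380387 to 80381166 (score 497) likewise had P19 CTCFL and no CTCF in either line, while chromosome 17 63848502 to 63849701 (score 516) and chromosome 5 22924214 to 22924428 (score 440) had no P19 peak. In P19 the strongest such sites, chromosome 5 33617544 to 33618171 (score 309), chromosome 11 98724360 to 98725305 (score 291), chromosome 9 75289290 to 75289742 (score 289) and chromosome 11 23155042 to 23156062 (score 258), were bound by both factors in 3T3. Chromosome 2 73108450 to 73109189 (score 274) and chromosome 2 158436236 to 158437166 (score 269) had no 3T3 peak. CTCFL without CTCF in both lines was found at 87 of the 3T3 peaks, led by chromosome 11 97276797 to 97277645 (374 in 3T3, 226 in P19), the chromosome 10 site above, and chromosome 9 107436248 to 107436545 (323 and 121).

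Merging all peaks that touched gave 65700 regions. CTCF in 3T3 alone made up 19370, CTCF in both lines without CTCFL 13987, and CTCF in P19 alone 12880. CTCFL in 3T3 alone accounted for 6278 regions, and both factors in 3T3 with nothing in P19 for 5984. P19 CTCFL alone made up 920 and both factors in P19 alone 849. Peaks of all 4 lists met in 1353 regions.

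**Figure D3:**
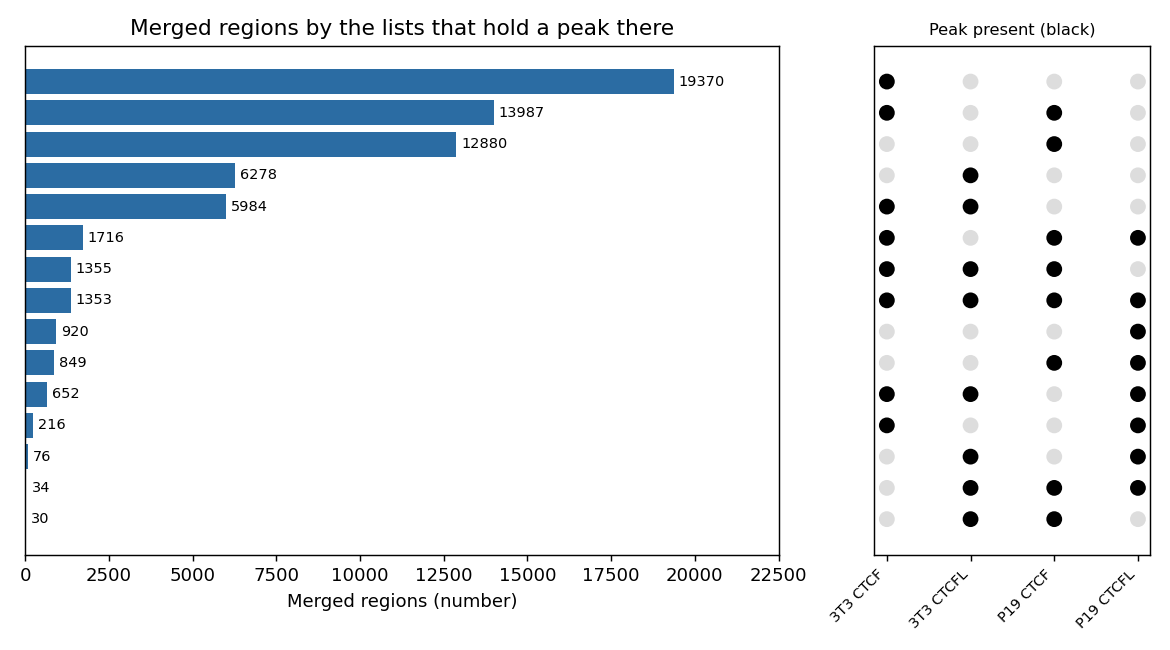
Number of merged regions (x axis) for each combination of the 4 peak lists, with black dots for the lists that hold a peak there. CTCF in 3T3 alone is the largest class with 19370 regions, and 1353 regions hold a peak of every list.

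The share of CTCFL peaks on CTCF sites was lower in 3T3 than in P19 on the full lists, with a difference of −6.31 points (−7.72 to −4.89). On lists of 5866 peaks each the direction turned, with 45.9% in 3T3 (44.6 to 47.1) and 28.1% in P19 (27.0 to 29.3), a difference of 17.7 points (16.0 to 19.5). At that length the P19 CTCFL list kept all its peaks, weak ones included, whereas the 3T3 CTCFL list was cut from 16764 peaks to its strongest. The direction also turned when peaks had to score at least 100, to 12.4 points with the limit in both lists and 6.46 points with the limit in the CTCFL list. That limit kept 6010 of 16764 CTCFL peaks in 3T3 and 1686 of 5866 in P19. Of the CTCF peaks it kept 24157 of 45653 in 3T3 and 19054 of 32277 in P19. Scores depend on depth and control library, so 1 limit does not cut the lists of the lines alike. The lists therefore gave no stable order of the lines.

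By chromosome, CTCF peaks were densest on chromosome 11 in both lines, at 29.9 per Mb in 3T3 and 21.4 per Mb in P19, and sparsest on X, at 4.50 and 4.46 per Mb. CTCFL was densest on chromosome 19 in 3T3 (12.8 per Mb) and on chromosome 11 in P19 (5.79 per Mb), and sparsest on X (1.30 and 0.391 per Mb). In P19 there were 27.0 CTCFL peaks per 100 CTCF peaks on chromosome 11, against 17.2 ± 3.82 (SD over the other 19 chromosomes), and 26.8 on chromosome 19. In 3T3 chromosome 11 had 38.2, against 35.9 ± 4.67. Chromosome 10 80000001 to 81000000 was the densest 1 Mb window for 3T3 CTCF (186 peaks), 3T3 CTCFL (83 peaks) and P19 CTCF (73 peaks), and chromosome 19 5000001 to 6000000 for P19 CTCFL (28 peaks).

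**Figure D4:**
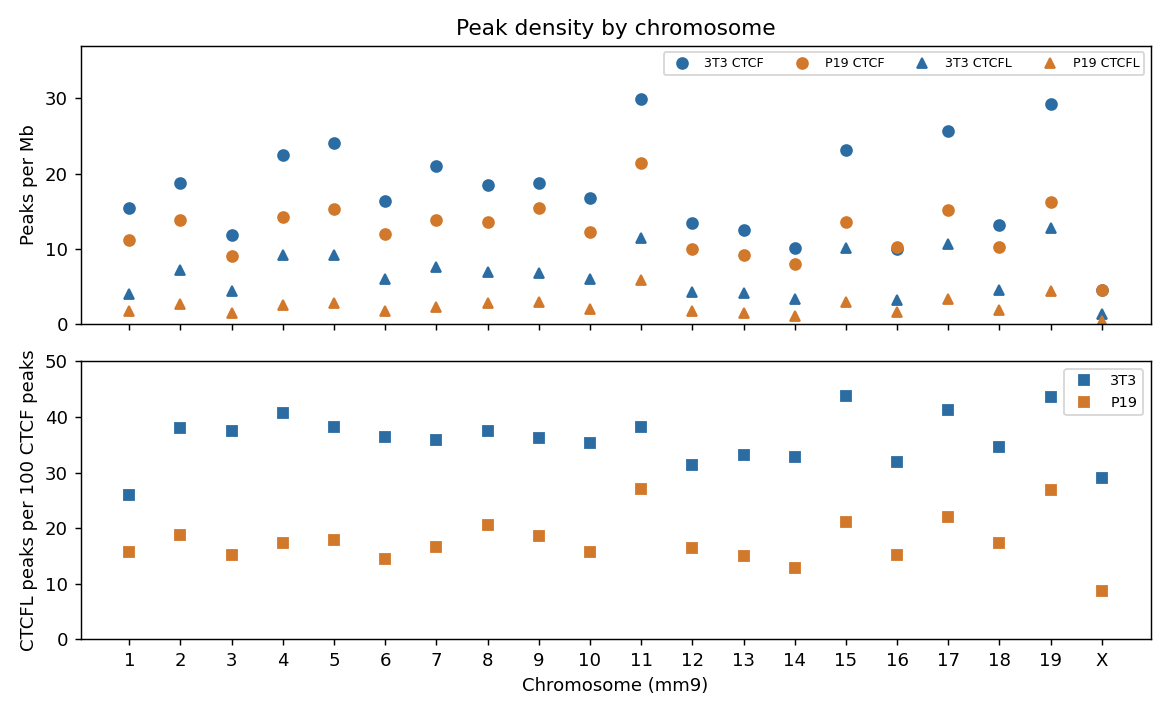
Peaks per Mb (top) and CTCFL peaks per 100 CTCF peaks (bottom) for each chromosome, with 3T3 in blue, P19 in orange, CTCF as circles and CTCFL as triangles. Chromosome 11 has the most CTCF peaks per Mb in both lines, and in P19 the most CTCFL peaks per 100 CTCF peaks, 27.0.

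Peaks of each list lay closer together than under uniform random placement. A neighbour of the same list lay within 10 kb of 61.9% of 3T3 CTCF peaks, 46.6% of 3T3 CTCFL peaks, 43.4% of P19 CTCF peaks and 19.2% of P19 CTCFL peaks. Random placement within chromosomes gave 31.9%, 14.0%, 23.1% and 5.37%. It ignores regional density, so closeness beyond that density was not tested. The next peak lay under 200 bp away for 5.30%, 6.93%, 1.12% and 0.784% of peaks in the same order, and whether such pairs are 1 enriched region was not examined. Denser lists have closer neighbours, so the 4 values are set against their own random value and not against each other.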

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

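The tests of P19 CTCFL overlap and of lower CTCFL scores below were chosen or reworded after the result was seen; the tests of score correlation and of narrow peaks were set before. The limit of the overlap test was changed after its first result, since it had taken any excess as excluding the explanation. A contrast was singled out where it had opposite signs in the cell lines, which held for 2 of 6 contrasts, and the difference between the lines was not tested across replicates.

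CTCF peaks with CTCFL were CTCF peaks of the other line less often than those without in 3T3, by −17.4 points, and more often in P19, by 22.6 points. Averaged over score groups these were −37.7 and 10.3 points, so in P19 score may account for a part of the difference. Score and width are no candidates in 3T3, since the peaks with CTCFL scored higher and were wider, and among peaks without CTCFL recurrence was higher in the highest group of score (91.5%) than in the lowest (22.5%) and in the widest group (48.9%) than in the narrowest (10.5%). One signal recovered by both antibodies may contribute, since the scores of CTCF and CTCFL correlated across 3T3 sites without P19 CTCF (Spearman's rho 0.444, 0.425 to 0.464), but sites with P19 CTCF had 0.555 and genuine joint binding would also give a correlation. That these sites were out of reach of both factors in P19 stays open: 10.1% (9.38 to 10.8) had a P19 CTCFL peak, above the 1.50% of sites with CTCF alone, yet the rest had neither factor, and the P19 CTCFL list is short. A difference of the lines or of CTCFL level, and an unmatched control library, remain open as untested.

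CTCFL peaks with CTCF recurred as CTCFL peaks of the other line more often than those without in 3T3, by 18.2 points (12.8 with peak centres within 200 bp), and less often in P19, by −4.77 points. For 3T3, narrow peaks are argued against as the whole cause, because among peaks of at least 200 bp the recurrence of CTCFL-only peaks was 0.119 (0.0992 to 0.143) times that of shared peaks. Lower scores are argued against as the whole cause. The gap was 8.93 points (8.07 to 9.85) averaged over score groups, weighted by the CTCFL-only peaks of each. The drop from 18.2 leaves room for a part. Averaged in the same way, the P19 contrast was −10.7 points, larger in size than −4.77 and of the same sign. Background peaks of either CTCFL list were not tested and stay open, as does a difference between the lines.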

How the results depend on the processing

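No paired analysis was possible because each group had 1 library, so the groups share fewer than 2 replicate numbers. Leaving out a replicate was not possible for the same reason, and the promoter and motif alternatives were not run for want of an annotation and genome of the same build. Of the values under alternatives set before the data were examined, 23 stayed within the interval of the reported value, 74 moved beyond it and 3 reversed. Of those under alternatives added after seeing the data, 12 stayed and 22 moved. Autosomes alone, run for the overlap shares, their difference and the recurrence contrasts, gave values within the interval for each of these. The cause of each shift was not tested, except that score limits and equal lengths remove weak peaks by construction. Read depth is unknown, so its effect on list length cannot be separated from binding.

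Shares are given in the order CTCFL at CTCF in 3T3 and P19, CTCF at CTCFL in 3T3 and P19, P19 CTCF at 3T3 CTCF, P19 CTCFL at 3T3 CTCFL, and the 3T3 minus P19 difference of the first pair in points. With peak centres within 200 bp they were 50, 61.7, 18.3, 11.2, 53.1, 29.6% and −11.7. A gap of up to 1000 bp gave 68.8, 70.8, 27.0, 13.7, 60.8, 40.9% and −2.01. Scores of at least 100 in both lists gave 78.1, 65.7, 18.8, 5.85, 54.5, 41.4% and a reversed difference of 12.4. The limit in the first list alone gave 86.8, 80.3, 30.3, 16.6, 70.3, 51.5% and a reversed difference of 6.46. Lists of equal length gave 45.9, 28.1, 43.4, 27.9, 31.3, 26.7% and a reversed difference of 17.7. Covering at least 50% of the shorter peak moved only the 3T3 shares, to 59.3% for CTCFL at CTCF and 20.3% for CTCF at CTCFL. Resizing to 400 bp moved 3T3 CTCFL at CTCF to 60.01% and P19 CTCF at 3T3 CTCF to 56.4%. CTCFL peaks of at least 200 bp, an added alternative, gave 66.3% for 3T3 CTCFL at CTCF.

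The share of pairs in which the peak with the partner had the higher score stayed above 50% throughout. With centres within 200 bp it was 71.8% for 3T3 CTCF, 70.6% for 3T3 CTCFL and 61.9% for P19 CTCFL. Scores of at least 100 gave 77.6, 77.1, 70.5 and 58.6% for 3T3 CTCF, 3T3 CTCFL, P19 CTCF and P19 CTCFL. Within 4 groups of width it was 63.6, 68.7 and 67.4% for the first 3 lists. For width, centres within 200 bp gave 72.5, 65.7, 61.2 and 52.5%, and 4 groups of score 70.1, 63.6, 57.3 and 51.5%, in the order of the 4 lists. Scores of at least 100 gave 79.9% for 3T3 CTCF, 69.1% for 3T3 CTCFL and 52.1% for P19 CTCFL.

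3T3 CTCFL-only peaks at P19 CTCFL and at P19 CTCF were 4.02% and 3.29% with centres within 200 bp, and 1.76% and 0.936% with no CTCF within 1000 bp. At P19 CTCFL they were 5.41% with scores of at least 100 and 2.59% with widths of at least 200 bp. P19 CTCFL-only peaks at 3T3 CTCFL and CTCF were 31.7% and 35.4% with centres within 200 bp, and 55.7% and 65.4% with scores of at least 100. The recurrence of CTCF peaks with CTCFL minus those without, under added alternatives, was −18.6 points in 3T3 and 15.1 in P19 with centres within 200 bp, −19.1 and 20.4 with resized peaks, and −20.0 in 3T3 with scores of at least 100. It was −37.7 in 3T3 and 10.3 in P19 averaged over 10 groups of score, and −25.3 and 17.4 over 10 groups of width. The same contrast for 3T3 CTCFL peaks with and without CTCF was 12.8 points with centres within 200 bp, 12.9 with scores of at least 100, 16.4 with resized peaks and 8.93 averaged over 10 groups of score. Neighbours within 5 kb were found for 46.0, 35.7, 26.8 and 11.5% of 3T3 CTCF, 3T3 CTCFL, P19 CTCF and P19 CTCFL peaks, and within 50 kb for 90.9, 77.9, 83.5 and 48.5%.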

Other observations

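The tests of one amplified segment below were chosen after the result was seen, and the test of chromosome copies before. Chromosome 11 held 12.02% of P19 CTCFL peaks (11.2 to 12.9) and 8.08% of P19 CTCF peaks (7.78 to 8.38). Of the 100 highest scoring peaks, 22 for P19 CTCFL and 26 for P19 CTCF lay there. For 3T3 CTCFL and CTCF these were 9 and 5, although scores near the top of the 3T3 lists do not rank peaks. The median CTCF score on chromosome 11 and on the others was 131 and 116 in P19, and 108 and 104 in 3T3. A single amplified segment is argued against as the whole cause, since 13 of 13 windows of 10 Mb along the chromosome exceeded the genome median of 15.9 CTCFL peaks per 100 CTCF peaks. The windows were uneven, from 17.5 to 49.2, and leaving out the 4 highest lowered the chromosome 11 ratio from 27.0 to 23.6, against 17.2 ± 3.82 (SD) on the other 19 chromosomes with all windows kept, so a segment could add to the excess. More copies of the whole chromosome in P19 stay open, since the test set for them could not decide. At CTCF sites of both lines the P19 minus 3T3 score percentile was −1.61 on chromosome 11, 1.31 SD above the mean of the other chromosomes. It was higher on chromosomes 16 (1.65) and 9 (−1.40), which had ordinary ratios of 15.2 and 18.5 CTCFL peaks per 100 CTCF peaks. Chromosome 19 had nearly the same ratio as chromosome 11 with a percentile difference of −7.88, and gene density was not analysed here.

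CTCFL and CTCF scores correlated across shared sites in 3T3 (Spearman's rho 0.480, 0.464 to 0.497, over 10270 peaks) and in P19 (0.153, 0.124 to 0.185, over 3964 peaks), both across peaks and not across replicates. The lower and upper quartiles of the score of CTCF peaks with CTCFL were 102 and 825 in 3T3, and 113 and 301 in P19. A narrower spread can lower a rank correlation, so these values do not order the lines. Peaks under 200 bp made up 31.0% of 3T3 CTCFL peaks without CTCF (29.9 to 32.2) and 14.0% of those with CTCF (13.3 to 14.7). The 3T3 CTCF list had the same order, with 15.8% of peaks without CTCFL and 4.72% of those with it. None of the 5866 P19 CTCFL peaks was that narrow, and of the P19 CTCF peaks only 3, all without CTCFL.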
